A study of Mus musculus with 16 samples.

How the data were processed

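The study measured messenger RNA in the facial prominences, the tissue buds that grow and fuse to form the face, of C57BL/6 mouse embryos at embryonic day 12. Per the labels' protocols, the surface ectoderm and the mesenchyme beneath it were separated surgically, RNA was taken with Trizol, and libraries followed standard Illumina protocols. The 4 groups were wild-type (WT) ectoderm, ectoderm of embryos homozygous for a knockout (KO) of Esrp1, WT mesenchyme and KO mesenchyme. Each group had 4 libraries, 16 in all, and each library came from a pool of 6 to 7 embryos. The labels list 1 index barcode for 11 libraries and 2 barcodes for 5 libraries. The libraries with 2 barcodes numbered 1 in WT ectoderm, 2 in KO ectoderm, 0 in WT mesenchyme and 2 in KO mesenchyme.

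The values come from a table deposited by the authors that gives TPM (a unit that corrects for sequencing depth and transcript length) per gene symbol, with 1 column per group. STAR 2.5.2a, kallisto 0.43.0 and the mouse genome build mm10 are named in the submitters' processing notes. Which tool gave these values, the transcript annotation, the step from transcripts to genes and the way the 4 libraries of a group were combined are not given in the sources used here. TPM keep no record of depth, so the depth behind each value is unknown. The table had 30391 rows with 30286 distinct symbols, and 5972 rows were at 0 in all 4 groups. Of 103 symbols found in several rows, 54 had identical values in each, and the row with the highest sum was kept. The columns added to 917993 TPM in WT ectoderm, 955495 in KO ectoderm, 969156 in WT mesenchyme and 977371 in KO mesenchyme.

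A model with the library as the unit had been chosen before the data were examined (limma on log2 TPM with the kind of index as a covariate). It needs a value per library and was not run, and no p-value, standard deviation or standard error is given anywhere. The gene lists and the genes always named were fixed before the data were examined. The sizes used for counting were set after it was seen that the table holds 1 value per group. The log2 ratio of a gene was taken between values of TPM plus 1, which understates the change of genes with low values. A gene entered a comparison where its mean over the groups compared was at least 1 TPM. Genes were counted at 1.5-fold or more between KO and WT, and at 2-fold or more between layers and between the KO effects of the layers (ectoderm effect minus mesenchyme effect). At these sizes "higher" and "lower" describe the deposited values and not a test.

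The 31 lists covered signalling pathways, epithelial, mesenchymal and patterning genes, genes of orofacial clefts, splicing, basement membrane, growth, stress and metabolism. Markers of other cell types and sex-linked genes (Xist and Y-linked genes) made up the rest. A list was summarised by the median log2 ratio of its members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Lists with at least 5 measured members were placed this way, and those below the 2.5 or above the 97.5 percentile were called outside the central 95%. Of 30 such lists, 1.5 would fall outside by chance if genes varied independently. Genes of a list vary together, so the percentile describes these libraries and is not a test.

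Named genes were to pass an adjusted p, so size took its place: the 10 highest and 10 lowest log2 ratios per KO comparison with at least 5 TPM in the higher group, the 10 largest layer differences in WT at 10 TPM or more, the 5 largest differences between the KO effects in each direction, up to 4 members of each list beyond 1.5-fold (otherwise 2), and 24 genes fixed in advance. Because many of the lowest and highest were predicted gene models or processed pseudogenes, which share reads with their parent genes, the 10 highest and lowest protein-coding genes without such names were added after their values were seen. Genes outside these sets are named in the text as members of a list or were chosen after their values were seen. A few genes that these rules take are not reported here.

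Gene positions, types, transcript length and transcript GC content were taken from GENCODE M21 on GRCm38, the assembly also called mm10. Symbols matched for 29994 of 30286 (99.0%). A trend with GC content was fitted by lowess (fraction 0.3) on genes with a mean of at least 5 TPM and subtracted. The same was done for log2 length, and for GC and length one after the other. GC content was known for every tested member of the 30 lists and for 99.2% of all genes tested. The share of mesenchyme RNA that would account for the gain of a gene in KO ectoderm was computed as KO ectoderm minus WT ectoderm, in percent of WT mesenchyme minus WT ectoderm, for genes at least 5-fold higher in WT mesenchyme. For red blood cell genes the share was taken over those at 100 TPM or more in WT mesenchyme, without the 5-fold limit. The median share of the mesenchyme list, taken of the WT mesenchyme values, was then subtracted from KO ectoderm as an alternative. Tissue carried over from KO embryos would have the KO mesenchyme values, and a subtraction of those was not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

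The steps were tested on simulated data made from the real values, with 200 genes changed 2-fold, noise of 0.15 on the log2 scale and a planted GC trend. In the ectoderm simulation 100% of 66 raised and 100% of 60 lowered genes at 10 TPM or more were recovered, and in the mesenchyme simulation 100% of 67 and 98.5% of 68. The GC correction lowered the share of unchanged genes beyond 1.5-fold from 1.81% to 0.0075% in ectoderm and from 1.72% to 0.0072% in mesenchyme. In both layers the planted trend fell with GC, while the real trend rises with GC in ectoderm. Noise of this size makes such rates nearly certain, so they do not carry over to the real values. There the median absolute deviation of the log2 ratios was 0.25 in mesenchyme before any correction. In a simulation without the GC trend and without changed genes, a planted share of 8% of WT mesenchyme was estimated at 8.34%. The list percentiles were also simulated without the GC trend, and genes varied independently. Of the 30 fixed lists, which may hold some of the changed genes, 2 in ectoderm and 1 in mesenchyme fell outside the central 95%. How the percentiles behave under a GC trend was not simulated. The alternatives tried were pseudocounts of 0.1 and 5, no filter or a filter of 5 TPM, median ratio scaling, quantile normalization, the corrections above, sums over distinct rows of a symbol and protein-coding genes only.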

Results

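RNA was measured in facial ectoderm and facial mesenchyme of WT and Esrp1 KO mouse embryos at embryonic day 12. Esrp1 encodes a splicing regulator of epithelial cells. The study's title places the work on cleft lip and palate and on Wnt signalling between the layers. Each of the 4 groups had 4 libraries, and the deposited table gives 1 TPM value per group. The differences below therefore have no replicate check, and values are printed without an error. Rows at 1 TPM or more numbered 13711 in WT ectoderm, 14174 in KO ectoderm, 14198 in WT mesenchyme and 14317 in KO mesenchyme. Mitochondrially encoded genes made up 7.99%, 7.41%, 7.19% and 9.59% of the column sums in that order.

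The separation of the layers was visible in WT tissue. Keratins and junction genes of surface epithelium were the genes most enriched in ectoderm, led by Krt5 (702 TPM in ectoderm and 2.22 in mesenchyme), Krt15 (321 and 0.66) and Krt14 (524 and 2.43). Perp, Cdh1, Wnt7b, Esrp1, Gjb2, Cldn4 and Dsp completed the 10 highest, with log2 ratios from 6.30 to 6.92. Mesenchyme was led by Mab21l2 (158 TPM against 3.24 in ectoderm), Prrx1 (293 against 9.22), Cdh5 (55.6 against 1.02), Frzb, Col3a1, Actc1, Col6a2, Col1a2, Pdgfra and Cd248. These include collagens, a cadherin of blood vessels and an actin of muscle. At 2-fold or more, 980 genes were higher in WT ectoderm and 1718 in WT mesenchyme, of 14242 measured. Between the KO layers the counts were 1305 and 992 of 14411.

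Esrp1 was lower in KO ectoderm, at 62.9 TPM against 170 in WT, a log2 ratio of -1.42. In mesenchyme the gene was at 1.01 TPM in WT and 1.0 in KO. Esrp1 lies on chromosome 4 (11331933 to 11386783, minus strand, GRCm38). The labels do not say which part of the gene is deleted, and the value in KO ectoderm, 37.0% of WT, does not separate transcripts with and without the deleted part. Its paralog Esrp2 on chromosome 8 (106130319 to 106136974) was at 71.8 TPM in WT ectoderm and 76.5 in KO. None of the 19 measured genes known to be spliced by Esrp proteins was 1.5-fold apart in ectoderm, and their median log2 ratio was 0.02. The largest differences among them were in Exoc7 (38.1 to 47.2 TPM) and Slk (48.5 to 39.4 TPM). Fgfr2, a receptor with epithelial and mesenchymal splice forms, was at 447 TPM in WT ectoderm and 366 in KO. Values per gene do not separate its forms. Splicing regulators as a group had a median of 0.00 in ectoderm (32 members, 2 higher) and -0.03 in mesenchyme (35 members, 1 higher and 2 lower, and 2 higher and 0 lower after correction for transcript GC).

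Most Wnt ligands of the ectoderm, and Shh, had lower values in KO ectoderm. Wnt3a, a ligand of canonical Wnt signalling, was at 10.1 TPM in WT and 5.01 in KO (log2 ratio -0.88), and Wnt7a at 10.2 and 6.16 (-0.65). Ligands with smaller differences, all within 1.5-fold, were also lower: Wnt7b was at 131 and 90.1 TPM, Wnt4 at 90.4 and 65.3, Wnt9b at 50.7 and 34.7, Wnt3 at 44.9 and 31.3, Wnt10b at 38.9 and 27.95, Wnt6 at 103 and 89.1 and Wnt10a at 6.31 and 5.41. Wnt3 and Wnt9b are neighbours on chromosome 11 (103774150 to 103817957 and 103727364 to 103749821) with established roles in lip formation. Shh, the hedgehog ligand of the oral and facial epithelium, was at 34.0 TPM in WT ectoderm and 20.5 in KO, a log2 ratio of -0.71, and of -0.55, within 1.5-fold, after subtraction of the share of mesenchyme RNA described below.

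Of 14 measured Wnt ligands, 2 were at least 1.5-fold lower (Wnt3a and Wnt7a) and 2 at least 1.5-fold higher (Wnt11, 1.38 to 3.83 TPM, and Wnt5a, 33.7 to 57.3 TPM). After correction for transcript GC 5 were lower and 2 higher, and after subtraction of the mesenchyme share 1 lower (Wnt3a) and 1 higher (Wnt11). The median of the list was -0.34, at the 0 percentile of random lists, and -0.21 after the subtraction. Among the 9 ligands with more TPM in WT ectoderm than in mesenchyme and at least 5 TPM there, a set chosen after values were seen, every log2 ratio was below 0, from -0.88 to -0.19 with a median of -0.51. This median lay at the 0.08 percentile of random draws from 369 genes enriched in ectoderm, whose own median was -0.10. Fgf8 (26.3 and 25.1 TPM) and Fgf9 (25.3 and 25.8 TPM) were nearly level between WT and KO. The Fgf ligands and receptors had a median of 0.10, with 3 higher, among them Fgf17 (3.54 to 8.05 TPM), and 1 lower of 13. After the subtraction 1 was higher and 1 lower.

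**Figure D1:**
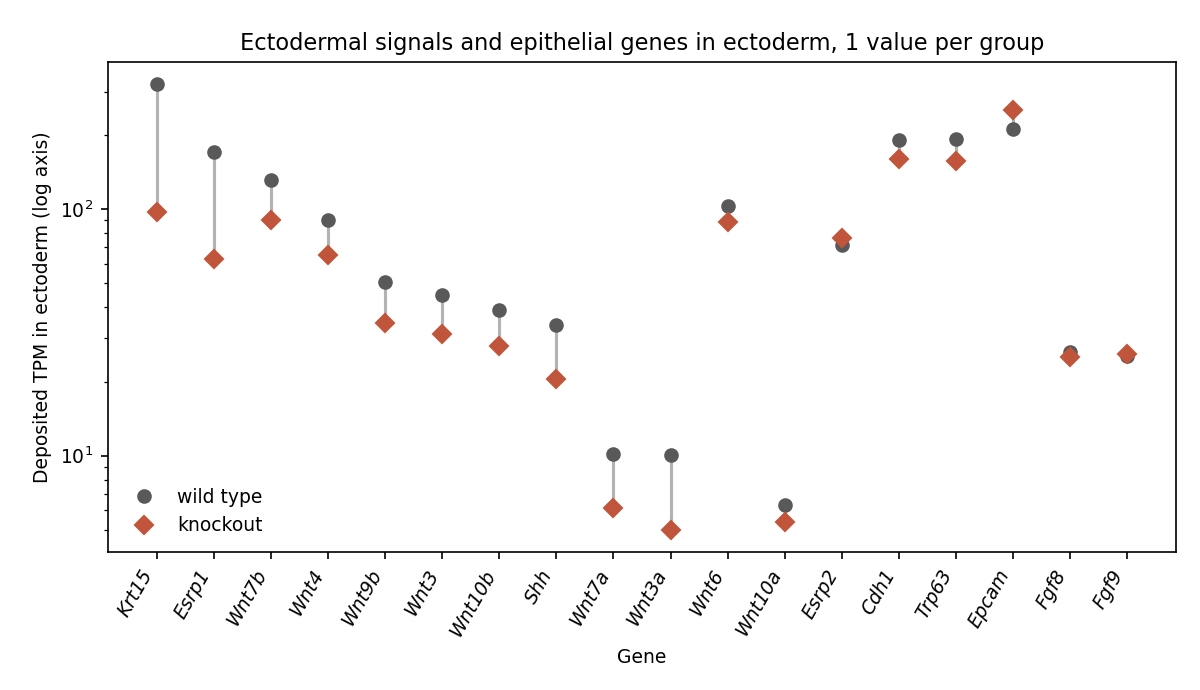
Deposited TPM in WT (circles) and KO (diamonds) ectoderm on a log axis for Esrp1, Krt15, Shh, the 9 ectodermal Wnt ligands and epithelial genes, with 1 value per group and no error. Esrp1 lies at 170 TPM in WT and 62.9 in KO, and each of the 9 ligands is lower in KO.

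Most epithelial genes of KO ectoderm were close to WT. Krt15, a keratin of basal cells, had the lowest ratio of the protein-coding genes that are not predicted models or pseudogene-like, at 97.9 TPM against 321 in WT (log2 ratio -1.70). Cdh1 (190 and 160 TPM), Trp63 (193 and 156 TPM) and Epcam (212 and 253 TPM), genes of epithelial adhesion and identity, were all within 1.5-fold. Of 40 measured members of the epithelial core list, Krt15 was the 1 lower gene and Cldn3 the 1 higher gene (17.7 to 28.9 TPM), and the median was -0.04 (percentile 0.05). The median was 0.10, above the central 95%, after subtraction of the share of mesenchyme RNA estimated from the mesenchyme core genes. Tfap2a, a transcription factor of surface ectoderm, was at 73.4 and 59.8 TPM. Among 15 periderm and epidermal differentiation genes, the keratins Krt6a (14.8 to 27.8 TPM) and Krt17 (28.0 to 45.9 TPM) and Sprr1a (1.09 to 3.35 TPM) were higher, none was lower, and the median was 0.00. The other protein-coding genes lowest in KO ectoderm were Esrp1, Fam19a4 (8.68 to 3.15 TPM), Lars2 (1366 to 632 TPM), Plbd1, Wnt3a, Sap18, Rhbdl3, Gdpd2 and Nr2e3 (12.3 to 6.94 TPM).

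Genes of the mesenchyme were higher in KO ectoderm. The 10 highest genes were Mab21l2 (3.24 to 17.7 TPM, log2 ratio 2.14), Hand2 (0.79 to 6.84 TPM, 2.13), Aldh1a2, Prrx1 (9.22 to 40.4 TPM), Col1a1 (5.61 to 24.5 TPM), Frzb, Emcn, Tnnt1, Col3a1 (31.0 to 118 TPM) and Col6a2. Of 29 mesenchyme core genes, 21 were at least 1.5-fold higher and none lower, with a median of 1.13. Vim, an intermediate filament of mesenchymal cells, was at 174 and 256 TPM. Endothelial markers such as Cdh5 (1.02 to 6.16 TPM) were higher in 14 of 15 cases with a median of 1.19. Skeletal muscle markers such as Myog (1.72 to 7.32 TPM) and Actc1 (5.25 to 21.9 TPM) were higher in 14 of 15 with a median of 1.30.

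Facial patterning transcription factors followed, with 17 of 27 higher and a median of 0.93, among them Lhx8 (1.20 to 7.09 TPM), Lhx6 and Shox2. Cartilage and bone markers had 4 of 13 higher (Col9a1, 3.06 to 12.0 TPM, Col9a2, Col9a3 and Matn4) and a median of 0.34, and macrophage and leukocyte markers had 5 of 12 higher (C1qc, 1.85 to 4.04 TPM) and a median of 0.48. Wnt receptors and secreted modulators had 7 of 25 higher and a median of 0.21, including Frzb (1.64 to 9.16 TPM) and Sfrp2 (24.2 to 52.5 TPM). Canonical Wnt feedback and target genes had 2 of 18 higher, Dkk1 and Nkd2 (3.0 to 5.89 TPM), and a median of 0.22. After the subtraction both turned, Dkk1 to -0.57 and Nkd2 to -0.19. Each of these lists lay above the 99 percentile of random lists before the mesenchyme share was subtracted.

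Most genes with a gain in KO ectoderm had their higher level in WT mesenchyme. Of the 686 genes at least 1.5-fold higher in KO ectoderm, 390 (56.9%) were at least 5-fold higher in WT mesenchyme than in WT ectoderm, compared with 3.65% of all genes tested. The gain equalled 10.7% of the mesenchyme excess for the median mesenchyme core gene (quartiles 7.49 to 12.4, 24 genes), 10.1% for endothelial, 14.1% for muscle, 14.9% for patterning and 19.8% for cartilage and bone genes. Neuron markers gained 5.29% (quartiles 3.94 to 7.20, 6 genes), below the quartiles of the core genes. These shares refer to WT mesenchyme. Against KO mesenchyme, over sets of genes that differ in part, the medians were 13.8% for core, 15.5% for endothelial and 18.3% for muscle genes. They were 22.8% for patterning, 22.9% for cartilage and bone and 4.97% for neuron genes. In WT ectoderm the core genes already stood at a median 4.72% of their WT mesenchyme level. Red blood cell genes did not gain in the same way: Hbb-y was at 2250 TPM in WT ectoderm and 2294 in KO, and 1 of 13 members, Hbb-bh1, was higher (261 to 428 TPM). After subtraction of the share of the core list, the medians were -0.00 for the core list, -0.03 for endothelial (5 members left above the filter), -0.02 for Wnt feedback and target genes, 0.40 for patterning, 0.52 for muscle, 0.12 for cartilage and bone, 0.20 for macrophage markers and 0.05 for Wnt receptors and modulators. All of these except patterning and muscle were then within the central 95%. At least 1.5-fold higher were then 4 of 28 core, 10 of 26 patterning, 5 of 12 muscle, 2 of 12 macrophage, 3 of 12 cartilage and bone genes and 1 of 23 Wnt receptors, and 6 core genes were lower.

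**Figure D2:**
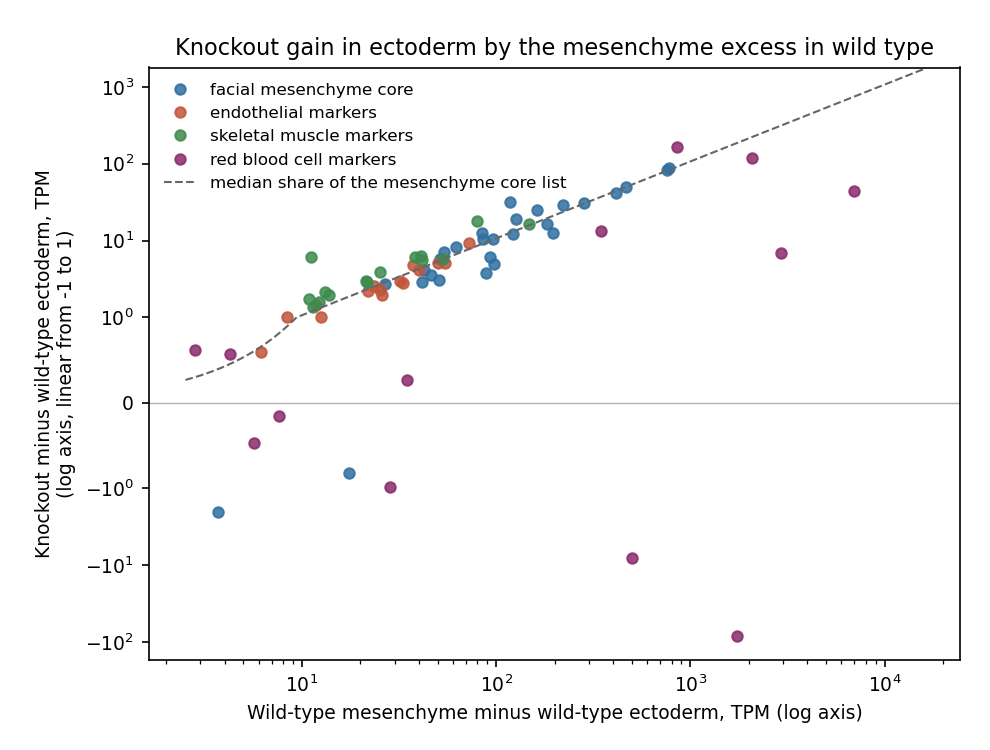
TPM in KO minus WT ectoderm (vertical, logarithmic beyond 1 and linear near 0) against TPM in WT mesenchyme minus WT ectoderm (horizontal, log axis) for members of 4 gene lists, 1 point per gene. The dashed line marks a gain of 10.7% of the mesenchyme excess, the median of the mesenchyme core list, and the most abundant red blood cell genes lie below it, apart from Hbb-bh1.

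Genes of the nasal and olfactory ectoderm were also higher in KO ectoderm, and most of these have low values in mesenchyme. Fezf1 (0.42 TPM in WT mesenchyme) was at 6.23 TPM in WT and 23.0 in KO (log2 ratio 1.73), Sp8 at 2.36 and 8.34, Six3 at 6.90 and 17.9 and Eya2 at 44.0 and 106. Of 14 members 12 were higher and none lower, with a median of 1.12, and of 0.86 after subtraction of the mesenchyme share. Neuron markers had a median of 0.52 with 6 of 13 higher, including Tubb3 (16.8 to 33.6 TPM) and Elavl4 (3.28 to 6.18 TPM), and of 0.29 after the subtraction.

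Part of the feedback genes and targets of Fgf signalling were higher in KO ectoderm. Etv4 (27.2 to 54.9 TPM) and Etv1 (6.03 to 12.9 TPM), transcription factors induced by Fgf, and Il17rd (9.25 to 19.3 TPM) and Spry4 (3.34 to 6.80 TPM), inhibitors of the pathway, had the largest ratios. Of 12 members 6 were higher and none lower by 1.5-fold, and 4 had ratios below 0, down to -0.34 (Egr1). The median was 0.57, and 0.65 after the subtraction. Bmp and Tgf-beta pathway genes had 8 of 28 higher, none lower and a median of 0.33, including the antagonist Grem1 (1.75 to 5.29 TPM). The ligand Bmp4 was at 20.3 and 29.6 TPM. Immediate early and stress genes had 4 of 21 higher and a median of 0.18, with the heat shock genes Hspa1a (6.80 to 20.9 TPM) and Hspa1b (12.7 to 30.1 TPM) first. Glycolysis and hypoxia genes had a median of 0.20 and ribosomal proteins of 0.12, with no member beyond 1.5-fold in either. These 5 lists lay above the 99 percentile of random lists, and ribosomal proteins had a median of 0.02, within the central 95%, after quantile normalization.

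The remaining lists were within the central 95% in ectoderm. Medians were 0.03 for the Hedgehog pathway (Foxf1 and Foxf2 higher, Shh lower, of 12, and none after the subtraction), 0.00 for orofacial cleft genes (8 of 37 higher, and 2 of 35 after the subtraction), 0.09 for basement membrane (5 of 25 higher, and 1 after the subtraction), 0.05 for the cell cycle (Mki67 at 90.2 and 94.9 TPM), 0.07 for p53 targets, 0.03 for cholesterol synthesis, 0.15 for Schwann cell and melanoblast markers and 0.00 for mitochondrially encoded genes. In total 686 genes were at least 1.5-fold higher and 63 lower in KO ectoderm, of 13935 measured, and the median log2 ratio of all genes was 0.05. Quantile normalization gave 469 higher and 131 lower. Of the 30 lists 15 lay above and 2 below the central 95%, against 1.5 expected by chance. After subtraction of the mesenchyme share 10 lay above and 3 below, the latter being Wnt ligands, red blood cell markers and splicing regulators. After correction for GC the Hedgehog pathway (-0.09) and periderm genes (-0.16) were also below the central 95%, and the cell cycle (0.03) above it.

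**Figure D3:**
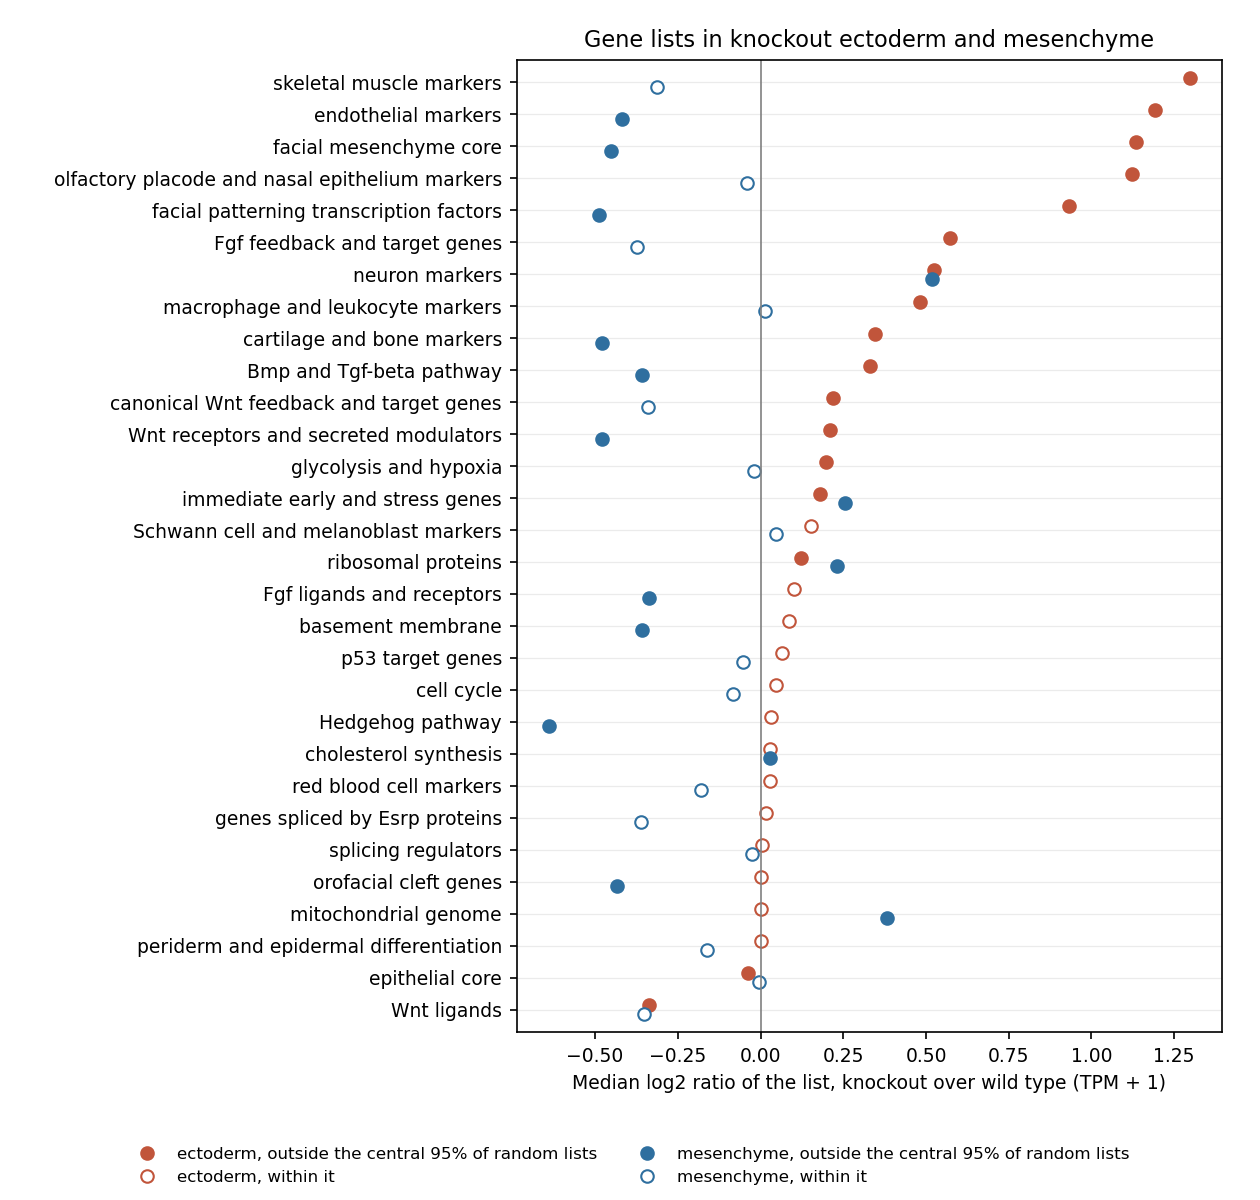
Median log2 ratio of KO over WT for each of 30 gene lists in ectoderm (red) and mesenchyme (blue), ordered by the ectoderm value, with filled points for lists outside the central 95% of random lists. Muscle, endothelial, mesenchyme core and olfactory genes lie above 1.1 in ectoderm, and the Hedgehog pathway is lowest in mesenchyme at -0.64.

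In KO mesenchyme, some genes of signalling pathways that shape the face were lower. Of 12 Hedgehog pathway genes 8 were at least 1.5-fold lower and none higher, with a median log2 ratio of -0.64. After correction for transcript GC 2 of the 12, Gli2 (-0.68) and Foxf1 (-0.68), were 1.5-fold lower, and the median was -0.28. The transcription factors Gli2 (41.2 to 17.2 TPM) and Gli1 (72.3 to 38.3 TPM) and the targets Foxf1 (18.2 to 8.37 TPM) and Foxf2 (19.3 to 9.08 TPM) were lowest. Lef1, a transcription factor and target of canonical Wnt signalling on chromosome 3 (131110471 to 131224356), was at 82.9 TPM in WT and 39.3 in KO (log2 ratio -1.06). Axin2, a feedback gene of the same pathway, was at 52.0 and 33.9 TPM (-0.60).

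Canonical Wnt feedback and target genes had 6 of 16 lower and none higher, also Tcf7 (11.6 to 5.74 TPM), Apcdd1 (140 to 77.0 TPM), Kremen1 and Nkd1, and a median of -0.34. This was at the 5.90 percentile, within the central 95%. After correction for transcript GC the ratio of Lef1 was -0.84, that of Axin2 -0.10 and the median of the list -0.07, and 2 of 16 members, Lef1 and Kremen1, were still 1.5-fold lower. Wnt receptors and secreted modulators had 7 of 26 lower and 1 higher, with a median of -0.48 (percentile 0.05), including Lrp5 (37.7 to 14.1 TPM), Ror2 and Sfrp2 (151 to 73.8 TPM). Wnt ligands had a median of -0.35 over 7 members (percentile 4.47, within the central 95%), with Wnt5b (12.0 to 6.62 TPM) and Wnt9a lower. After correction for GC the median was 0.07 and none was 1.5-fold lower.

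Part of the structural and patterning genes of the mesenchyme were lower as well. Of 29 core genes 11 were lower and none higher, with a median of -0.45 (percentile 0.02), led by Col1a1 (132 to 49.1 TPM), Col5a1 (82.4 to 32.3 TPM), Osr2 (59.8 to 25.5 TPM) and Pdgfrb. Patterning factors had 12 of 28 lower, such as Pitx1 (31.1 to 11.9 TPM) and Dlx5 (45.8 to 22.0 TPM), and 1 higher, Hoxa2 (2.72 to 8.01 TPM), with a median of -0.49. Genes with known roles in orofacial clefts had 10 of 31 lower and none higher, with a median of -0.43, among them Tgfb3 (28.4 to 13.6 TPM) and Sox9 (24.5 to 12.3 TPM). Cartilage and bone markers had 7 of 16 lower, 1 higher and a median of -0.48, with Alpl at 21.1 and 8.69 TPM and Sp7 at 10.2 and 4.92. Fgf ligands and receptors had 3 of 13 lower and a median of -0.34, including Fgfr1 (280 to 160 TPM). Fgf10, a ligand made by mesenchyme, was at 12.1 TPM in WT and 8.37 in KO, and Bmp4 at 60.1 and 44.2. These 5 lists, the Wnt receptors and the Hedgehog pathway stayed below the 2.5 percentile after correction for GC, at medians from -0.28 to -0.16. Fewer members were then 1.5-fold lower: 7 of 29 core, 3 of 28 patterning, 4 of 31 cleft, 3 of 16 cartilage and bone and 1 of 13 Fgf genes, and 2 of 26 Wnt receptors. After correction for GC and length the core list (-0.09, percentile 4.08) was within the central 95%.

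Basement membrane genes (8 of 24 lower, Hspg2 at 45.4 and 13.8 TPM, median -0.36), endothelial markers (7 of 19 lower, 1 higher, Plvap at 34.3 and 14.8 TPM, median -0.42) and Bmp and Tgf-beta genes (9 of 29 lower, 2 higher, median -0.36) were below the 2.5 percentile only before that correction. The Bmp and Tgf-beta median turned to 0.11 after it, and 4 of 24 basement membrane, 4 of 19 endothelial and 4 of 29 Bmp and Tgf-beta genes were still lower. Muscle markers had 7 of 21 lower, with Myod1 at 12.8 and 4.06 TPM and a median of -0.31 (percentile 3.76), and of -0.17, below the 2.5 percentile and with 2 of 21 lower, after correction for GC. Fgf feedback genes had 4 of 12 lower, with Etv5 at 35.8 and 18.2 TPM and Spry4 at 9.68 and 5.35, and a median of -0.37 (percentile 6.90), and 2 of 12 lower after correction for GC. Among the protein-coding genes lowest in KO mesenchyme were Cd248 (65.2 to 19.4 TPM), Ccl21b, Hspg2, Lrp1 (144 to 47.5 TPM), Clip3, Ubr4, Myod1, Polr2a (139 to 50.7 TPM) and Scaf1, with log2 ratios from -1.70 to -1.43.

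Some heat shock and immediate early genes and some neuron markers were higher in KO mesenchyme. The heat shock genes Hspa1a (0.60 to 18.4 TPM, log2 ratio 3.60) and Hspa1b (1.34 to 19.8 TPM, 3.15), both on chromosome 17, were the highest protein-coding genes, followed by Atf3 (1.87 to 11.7 TPM), Stmn4 (5.40 to 16.02 TPM), Fos (15.5 to 42.9 TPM), Uty, Fam98b, Dhx9, Ddx3y and Stmn3. Of 20 immediate early and stress genes 6 were higher, 1 lower and 13 within 1.5-fold, with a median of 0.25, and the median was 0.00 within the central 95% with a filter of 5 TPM. After correction for GC 11 of 20 were higher and none lower, with a median of 0.74. Neuron markers had 8 of 18 higher, none lower and a median of 0.52, including Dcx (5.67 to 12.9 TPM), Isl1 (13.0 to 25.6 TPM) and Snap25 (3.77 to 7.45 TPM), and 11 of 18 were higher after correction for GC. Ribosomal proteins had a median of 0.23, with Rpl10 beyond 1.5-fold (570 to 1043 TPM), and of 0.07, within the central 95%, after quantile normalization. After correction for GC 19 of 56 were beyond 1.5-fold and the median was 0.44. Mitochondrially encoded genes had a median of 0.38, with mt-Atp8 and mt-Nd3 (2467 to 3761 TPM) beyond 1.5-fold, and of 0.09 after correction for GC. The 4 measured Y-linked genes were higher in KO mesenchyme, with a median of 1.29 (Ddx3y, 15.4 to 39.6 TPM, Kdm5d, 12.2 to 29.4 TPM), and in KO ectoderm, with a median of 0.82 (Ddx3y, 14.3 to 28.2 TPM, Eif2s3y, 30.0 to 47.7 TPM). All 4 stayed at least 1.5-fold higher in both layers after correction for GC (in mesenchyme Ddx3y at 0.96 and Uty at 1.12). Xist, also on that list, had no value. The labels give no sex of the pooled embryos. A larger share of male embryos in the KO pools would raise all 4 in both layers, but the sex mix was not tested. It cannot be told apart from the KO in any difference given here.

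Other lists lay within the central 95% in mesenchyme, except cholesterol synthesis, whose median of 0.03 was at the 97.9 percentile although 5 of 20 members were lower. Medians were -0.08 for the cell cycle (5 of 40 lower, Plk1 at 83.1 and 40.4 TPM, and 1 after correction for GC), -0.05 for p53 targets (3 of 15 lower, 1 higher, and 0 lower, 2 higher after correction for GC), -0.02 for glycolysis and hypoxia, -0.36 for genes spliced by Esrp proteins (5 of 18 lower), -0.18 for red blood cell markers, 0.01 for macrophage markers, 0.05 for Schwann cell and melanoblast markers, -0.04 for olfactory, -0.00 for epithelial core and -0.16 for periderm genes. Genes spliced by Esrp proteins had a median of -0.11 after correction for GC, with none of 18 lower. After that correction glycolysis and hypoxia genes (0.30) and the epithelial core (0.31) were above the central 95%, and cholesterol synthesis (0.07, percentile 87.3, 0 of 20 lower) and mitochondrially encoded genes were within it.

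In total 1902 genes were at least 1.5-fold lower and 332 higher in KO mesenchyme, of 14233 measured, and the median of all genes was -0.12. The direction followed the GC content of the transcripts. Across 10911 genes, which are not independent replicates, the rank correlation of GC content and log2 ratio was -0.66, and the median ratio went from 0.21 in the 10% of genes with the lowest GC to -0.55 in the 10% with the highest. In ectoderm the correlation was 0.36 and the medians ran from -0.01 to 0.19. After correction for GC, 352 genes were lower and 664 higher in KO mesenchyme, and 326 of the 1883 lower genes with a GC value (17.3%) were still 1.5-fold lower. Quantile normalization gave 968 lower and 637 higher and moved the median of all genes to 0.02. Of the 30 lists 5 lay above and 10 below the central 95%.

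**Figure D4:**
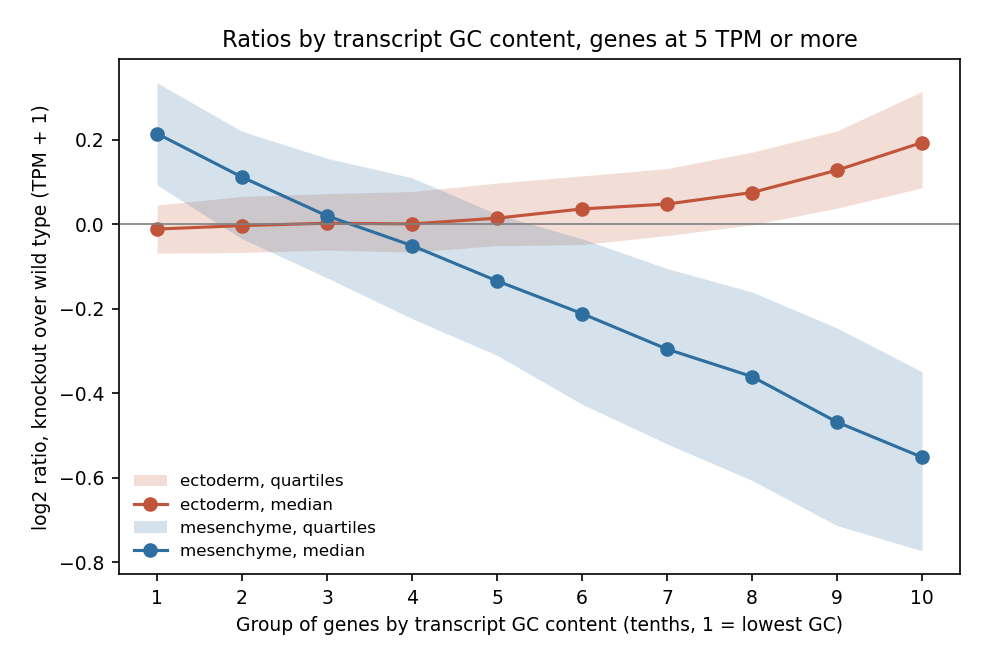
Log2 ratio of KO over WT (vertical, TPM plus 1) in 10 equal groups of genes ordered by transcript GC content (horizontal) in ectoderm (red) and mesenchyme (blue), with medians as points and quartiles as bands, for genes at 5 TPM or more. The mesenchyme medians go from 0.21 to -0.55 and the ectoderm medians from -0.01 to 0.19.

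Compared between the layers, part of the mesenchymal genes differed in opposite directions. Col1a1 was higher in KO ectoderm and lower in KO mesenchyme (difference of log2 ratios 3.35), as were Cd248 (3.29), Mab21l2 (3.18) and Ccl21b (3.06). After subtraction of the mesenchyme share the ectoderm ratio was 0.93 for Col1a1 and turned to -0.56 for Cd248 and -1.15 for Mab21l2. The share was taken of the WT mesenchyme values, 65.2 TPM for Cd248 and 158 for Mab21l2. In KO mesenchyme these genes were at 19.4 and 76.8 TPM. A subtraction of KO mesenchyme was not run, so both turns rest on that choice. Other mesenchymal genes higher in KO ectoderm were close to level in KO mesenchyme, such as Pdgfra (log2 ratio -0.05), Emcn (-0.01) and Prrx1 (-0.21). Of 13283 genes measured in both layers, 973 had an ectoderm effect at least 2-fold above the mesenchyme effect and 70 at least 2-fold below it. At 1.5-fold in each layer, 168 of the 644 genes higher in KO ectoderm were lower in KO mesenchyme, where independent lists would share 88.8. Higher in both were 42 genes (13.2 for independent lists), lower in both 6 (5.65), and lower in ectoderm and higher in mesenchyme 13 (0.840). Across genes the effects had a Pearson correlation of -0.12 and a rank correlation of -0.19. They were 0.00 and 0.02 after correction for GC, and 0.00 and -0.08 after subtraction of the mesenchyme share.

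Several of the largest ratios belonged to pseudogenes and predicted models, whose reads cannot be separated with certainty from near-identical genes. Rps12l1 was at 396 TPM in WT ectoderm and 30.3 in WT mesenchyme and listed at 0 in both KO groups, while its parent Rps12 was at 1292 TPM in WT ectoderm and 1932 in KO. Gm29013 was at 3.02 TPM in WT mesenchyme and 2561 in KO. Gm10241 was at 13.3 TPM in WT mesenchyme and listed at 0 in KO. In ectoderm Gm10273 (log2 ratio -2.81), Gm13167 (-2.51), Gm26992 (-2.41), BC002163 (-2.31), Rpl14-ps1 (-1.96) and Gm7332 (-1.81) were among the lowest. In mesenchyme Gm15899 (2.64), Gm18588 (2.57), Rpl14-ps1 (2.51), Gm28155 (2.32), Gm28437 (2.28) and Gm10254 (2.03) were among the highest, and BC002163 (-3.20), Gm13123 (-2.39), Gm10182 (-1.82), Gm6851 (-1.80), Gm9625 (-1.72) and Gm8730 (-1.69) among the lowest. Between the layers Gm29013 (-10.71), Rpl14-ps1 (-4.47), Gm13167 (-3.97) and Gm10273 (-3.60) had the largest differences in favour of mesenchyme, and no such difference is given for Rps12l1 and Gm10241, which are listed at 0 in a KO group. Of the 10 lowest genes by size, 5 in ectoderm and 8 in mesenchyme were not protein-coding in the annotation, as were 7 of the 10 highest in mesenchyme and 0 of the 10 highest in ectoderm.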

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

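Of the tests in this part, the shares of endothelial, red blood cell, muscle and neuron genes, the reading of endothelial genes against a mesenchymal state, the set of 9 Wnt ligands, and the corrections applied to genes and lists low in KO mesenchyme were chosen only after the result was seen, and the GC correction and the subtraction used by the others were added after the data were seen.

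Gene lists were singled out because they were outside the central 95% of random lists in both layers, above it in KO ectoderm and below it in KO mesenchyme. The difference of the medians was 1.61 for endothelial markers, 1.59 for facial mesenchyme core genes, 1.42 for facial patterning transcription factors, 0.82 for cartilage and bone markers, 0.69 for Wnt receptors and secreted modulators and 0.69 for Bmp and Tgf-beta pathway genes. These differences between the layers were not tested, since each group has 1 value. After subtraction of carried-over mesenchyme, cartilage and bone markers (0.12) and Wnt receptors (0.05) were within the central 95% in KO ectoderm. So were endothelial markers (-0.03), with 5 members left above the filter, and the core list (-0.00), which is near 0 by construction. After correction for GC endothelial markers (-0.13) and Bmp and Tgf-beta genes (0.11) were within it in KO mesenchyme. Facial patterning factors stayed outside in both (0.40 after subtraction and -0.23 after correction for GC), and Bmp and Tgf-beta genes stayed above in KO ectoderm (0.29).

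Genes of the mesenchyme, such as Prrx1 and Col3a1, were higher in KO ectoderm. A GC trend does not account for this, since the median of the mesenchyme core list was 1.04 after GC correction, and a mesenchymal state of the KO epithelial cells does not account for the endothelial genes that came with it at a median of 1.19. Mesenchyme carried over at the separation may be the source, because endothelial genes gained 10.1% of their WT mesenchyme excess, within the quartiles of the core genes. Against KO mesenchyme the medians were 15.5% for endothelial and 13.8% for core genes, and quartiles were not computed. Carried-over mesenchyme does not account for every part as a uniform sample of that layer. Against WT mesenchyme, neuron markers gained 5.29%, muscle genes 14.1%, patterning factors 14.9% and cartilage and bone genes 19.8%. The 7 red blood cell genes at 100 TPM or more in WT mesenchyme gained 0.635% (quartiles -0.69 to 4.74). They were taken without the limit to genes 5-fold higher in WT mesenchyme, so this share does not compare directly with the others. A biological effect of the loss of Esrp1 on part of these genes stays open and was not tested.

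Wnt ligands of the ectoderm had lower values in KO ectoderm, 2 of the 9 (Wnt3a and Wnt7a) by 1.5-fold or more. Dilution by carried-over mesenchyme does not account for the whole difference, as the median of the 9 ligands was -0.35 after the share was subtracted (-0.21 for the 14 ligands of the list fixed in advance, at the 0 percentile). The GC trend in ectoderm raises ratios of GC-rich genes, and correction for it moved the median of the 9 ligands down, from -0.51 to -0.65. That outcome followed from the direction of the trend, so it lends no separate support to the lower values. Olfactory genes such as Fezf1 and Sp8 were higher in the same tissue (median 0.86 after subtraction), and whether the KO pools held another mix of ectodermal regions was not tested. An effect of the loss of Esrp1 on the ligands also stays open and was not tested.

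Many genes, including Gli2, Lef1 and Col1a1, were lower in KO mesenchyme. A GC trend between the libraries may account for most single genes. Of those at least 1.5-fold lower after centring, 25.5% stayed so after GC correction. The trend does not account for the place of all lists, since 7 of the 10 below the 2.5 percentile stayed there after that correction. Their medians shrank, from between -0.64 and -0.34 to between -0.28 and -0.16. After correction for GC and length 6 of the 10 stayed, when the mesenchyme core list was lost. Length alone does not account for most of the genes lower after centring, as 74.4% stayed lower after correction for length. Without centring, where the shift of all genes counts too, 46.9% did, so this reading depends on the centring. After correction for GC a trend with log2 length remained in mesenchyme (rank correlation -0.26). Libraries with 2 barcodes number 0 in WT and 2 in KO mesenchyme. With 1 value per group the kind of index cannot be told apart from the KO. A comparison of the libraries with 1 barcode would need values per library. The test written before its result was seen was the rank correlation with GC in ectoderm after subtraction of the mesenchyme share (0.34). This correlation does not decide, since ectoderm has 1 and 2 such libraries. What made the GC trend, and an effect of the loss of Esrp1 on the lists that stayed low, were not tested.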

How the results depend on the processing

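The pseudocounts, filters, median ratio scaling and quantile normalization were planned, and the corrections for GC and length, the subtraction of carried-over mesenchyme, the sum of distinct rows and the limit to protein-coding genes were chosen after the data were seen. Median ratio scaling, no filter and the sum of distinct rows moved no count by more than 1.5 times. Of 91 named genes in ectoderm, 81 or more kept their direction and side of 1.5-fold under the pseudocounts, scalings and corrections, while under the subtraction 74 did, 9 crossed 1.5-fold and 5 turned direction. Of 77 in mesenchyme, 71 or more kept both under the corrections. No paired analysis was possible because the table holds 1 value per group, although groups share replicate numbers in the labels. Planned and not run for the same reason were the index kind as covariate, no index term, only libraries with 1 barcode, the replicate block, robust eBayes, leaving out each replicate, all 16 libraries in 1 fit, camera and fry, and counts at an adjusted p.

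Genes lower in KO ectoderm (63) numbered 118 with pseudocount 0.1, 29 with pseudocount 5, 40 with a filter of 5 TPM, 131 after quantile normalization, 40 among protein-coding genes and 95 after subtraction. Genes higher there (686) numbered 239 with pseudocount 5, 317 with the filter of 5 TPM and 363 after subtraction. Genes higher in KO mesenchyme (332) numbered 529 with pseudocount 0.1, 119 with pseudocount 5, 175 with the filter, 637 after quantile normalization, 664, 715 and 557 after correction for GC, for length and for both, and 195 among protein-coding genes. Genes lower there (1902) numbered 1139 with pseudocount 5, 968 after quantile normalization, and 352, 895 and 347 after correction for GC, for length and for both. KO effects at least 2-fold apart (973 and 70) numbered 458 with pseudocount 5, 589 after quantile normalization, 415, 605 and 381 after the 3 corrections and 688 after subtraction. Layer differences numbered 1482 (pseudocount 5) and 1771 (filter) in WT, against 980 and 1718 together, and 1155 (pseudocount 5) in KO, against 1305 and 992 together. Lists below the 2.5 percentile in KO ectoderm (2) numbered 4 with the filter of 5 TPM, 4 after correction for GC and 4 for GC and length. Lists above the central 95% in KO mesenchyme (5) numbered 3 after quantile normalization. A larger pseudocount shrinks ratios of low genes and a stricter filter tests fewer genes by construction. For the other settings the cause was not tested.

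Subtraction put on the other side of the middle of random lists the medians in KO ectoderm of Wnt feedback and target genes (-0.0240), the epithelial core (0.10), the mesenchyme core (-0.00405) and endothelial markers (-0.0282), and turned the sign of Cd248 (-0.56), Col1a2 (-0.0169), Frzb (-0.0361), Mab21l2 (-1.15) and Pdgfra (-0.33) among the named genes. Of list members in the text that were 1.5-fold apart in KO ectoderm, Dkk1 (-0.57), Nkd2 (-0.19), Pdgfrb (-2.25) and Ror2 (-0.08) also turned. All these turns rest on subtraction of WT mesenchyme, and a subtraction of KO mesenchyme was not run. In KO mesenchyme Cd248 (19.4 TPM), Col1a2 (224), Frzb (50.6) and Mab21l2 (76.8) had lower values than in WT. Pdgfra was nearly level (126 and 122 TPM). The core list is brought near 0 by construction, because its median share was subtracted. In KO mesenchyme the Bmp and Tgf-beta median was -0.0316 with the filter of 5 TPM and 0.11 after correction for GC, and that of mitochondrially encoded genes was 0.0853 after correction for GC and -0.0341 for GC and length, each on the other side of the middle of random lists. The cause was not tested.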
